A study of Mus musculus with 24 samples.

How the data were processed

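RNA from 24 mouse thyroid samples was hybridised to Affymetrix Mouse430A_2 arrays. Per the labels, RNA was extracted with a spin column kit, normal samples are pools of glands, and tumours are papillary, anaplastic or recurrent. The deposited values are log2 intensities of 22690 probe sets, made by the authors with RMA (background correction, quantile normalization and probe summarization) in Partek, per the submitters' processing notes, and versions of both are not given in the sources used here. Values ran from 2.71 to 14.96. Because RMA brings arrays towards a common distribution, a shift of all genes in one direction would not be seen, and very high levels are compressed. All arrays were deposited in the same matrix on the log2 scale, but their spread differed by title. The SD of values on anaplastic arrays was 2.37 to 2.39 with JK in the title and 2.49 to 2.50 without. On recurrent arrays it was 2.23 to 2.43 with JK in the title and 2.47 to 2.50 without.

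Probe sets were named through the platform annotation given with the data, in which 20393 had 1 gene symbol, 691 several and 1606 none. Symbols were updated by gene identifier with the RefSeq annotation of the mouse assembly GRCm38.p6, where 20364 matched and 29 kept their file symbol. That annotation also gave the order of 12370 genes along chromosomes, and its coordinates are not printed since the files name no build. Each of 12394 genes was represented by the probe set with the highest mean over all arrays. For the called genes the rule names, other probe sets were checked for the opposite sign. These numbered 1 of 32 in ATC against normal, 2 of 21 in PTC against normal and 2 of 35 in recurrent against normal. In the other comparisons they numbered 0, and 0 were opposite by over 1 on the log2 scale. Hgf, not called in PTC against normal, differed there by 0.10 with its other probe set and by -0.09 with the one used. Trp53, which the rule would name, was not analysed here, and 1 other gene of the rule is not reported here.

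Groups were taken from the tissue label. Replicate numbers follow the order of the records and pair nothing. Among 276 pairs of arrays 0 were identical, and the highest correlation was 0.994. A linear model with 4 group means was fitted to all 24 arrays with limma 3.58.1 (R 4.3.3, with the data.table package, version 1.17.8), and differences were tested with its moderated test and Benjamini-Hochberg adjustment over 12394 genes, called under 0.05. A fixed set of 23 gene lists with 394 genes, 354 of them measured, was tested with camera of limma at a preset correlation of 0.01, adjusted over the 23 lists of a comparison. The lists cover thyroid differentiation, MAPK output, mitosis and replication, epithelial, mesenchymal, fibroblast and matrix, TGF-beta, macrophage, neutrophil, T and NK cell, B and plasma cell, interferon and antigen presentation, endothelial, parathyroid, C-cell, skeletal muscle, adipocyte, trachea and cartilage, Hgf and Met, receptor tyrosine kinases with ligands, Met neighbours, p53 targets, and hypoxia with glycolysis. Several of them mark other tissues a dissected gland could carry along, and some genes stand in more than 1 list. With a correlation estimated for each list, 0 of 23 lists were called in any comparison. Comparisons with normal glands share the same 6 pools, and no overlap between comparisons is reported.

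The genes named are, for each comparison, the 8 largest rises and 8 largest falls among called genes, up to 3 called members of each list in the direction most of its called members moved, and Met, Hgf, Braf, Tg, Slc5a5, Dusp6 and Mki67 in every case; the text names a part of them. This rule, the lists, the tests and most alternatives were fixed before the data were examined. Single comparisons and correlations used exact permutation tests, two-sided, with SciPy 1.17.1, pandas 2.3.3 and Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

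The limma step was tested on simulated data with 200 changed genes among 12394, using each group's own spread. It recovered 56.0% of 2-fold and 87.0% of 4-fold changes for PTC against normal, with 1.38% unchanged genes among the calls. For ATC against normal these were 56.0%, 90.0% and 2.67%, for ATC against PTC 44.0%, 86.0% and 2.99%, for recurrent against ATC 47.0%, 92.0% and 16.8%, and for recurrent against normal 66.0%, 91.0% and 13.3%. The last 2 lie above the nominal 5%, since recurrent tumours vary more than the spread shared by the 4 groups. These shares depend on how many genes change, so with 200 changed genes they do not give the error rate of the real calls.

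Alternatives were a fit of the 2 groups alone, the title series as a block, each title series alone, means of probe sets, every probe set on its own, a filter on dim genes, quantile normalization again, centring on medians, a trended robust spread, array weights, a 2-fold threshold, the WT-titled pools alone and leaving out each array. Chosen after seeing the data were a block and a subset by bare-number titles and the omission of normal 5 and recurrent 2, 3 and 6. Runs of neighbouring genes were scored over windows of 5 genes against 1000 shuffled gene orders per array. DNA copy number, protein and tumour histology were not analysed here.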

Results

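Gene expression was measured with Affymetrix Mouse430A_2 arrays, which read transcripts with sets of short probes, on 24 RNA samples from mouse thyroids. The arrays held 6 pools of normal thyroid glands, 4 papillary thyroid cancers (PTC, a differentiated tumour type), 5 anaplastic thyroid cancers (ATC, an undifferentiated type) and 9 recurrent tumours. The series concerns tumours that come back after BRAF, a kinase of the MAPK cascade, is inactivated, and the roles of the receptor Met and its ligand Hgf. Deposited values are on the log2 scale, and 12394 genes were compared, each through 1 probe set. Array medians lay between 7.38 and 7.58, and the number of arrays limits the precision. Labels do not say whether the tumours came from separate animals, so the p-values measure the spread between these samples, technical spread included.

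Normal pools and PTC arrays were close to their own kind, with median correlations between arrays of a group of 0.988 and 0.989. The median was 0.963 in ATC and 0.886 in recurrent tumours. The mean SD of a gene within a group was 0.24 in normal, 0.19 in PTC, 0.35 in ATC and 0.67 in recurrent arrays on the log2 scale. Normal arrays are pools of glands and the tumour labels name no pooling, so the spread of normal arrays does not measure the same thing. Array titles fall into a JK series (4 normal, 4 PTC, 2 ATC and 3 recurrent arrays) and others (2 normal, 3 ATC and 6 recurrent arrays). The 4 normal pools of the JK series have WT in their titles, and the other 2 have Cre. The 3' minus 5' signal of Gapdh, a measure of RNA integrity and labelling, was 1.39 ± 0.23 (log2, SD, n = 4) in PTC and 0.72 ± 0.09 (SD, n = 4) in the normal pools of the JK series, and 0.64 to 0.98 in the other 2 pools. In ATC it was 0.82 to 0.96 on the 2 JK arrays and 0.06 to 0.15 on the other 3, and in recurrent tumours 0.36 to 1.07 on the 3 JK arrays and -0.02 to 0.17 on the other 6. The low values are those of arrays titled with a bare number, which hold ATC and recurrent tumours and no normal pool. Outside the JK series every normal pool is thus titled Cre and every tumour with a bare number. A block by title series joins these 2 kinds of title, so it does not set the bare-number arrays apart.

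**Figure D1:**
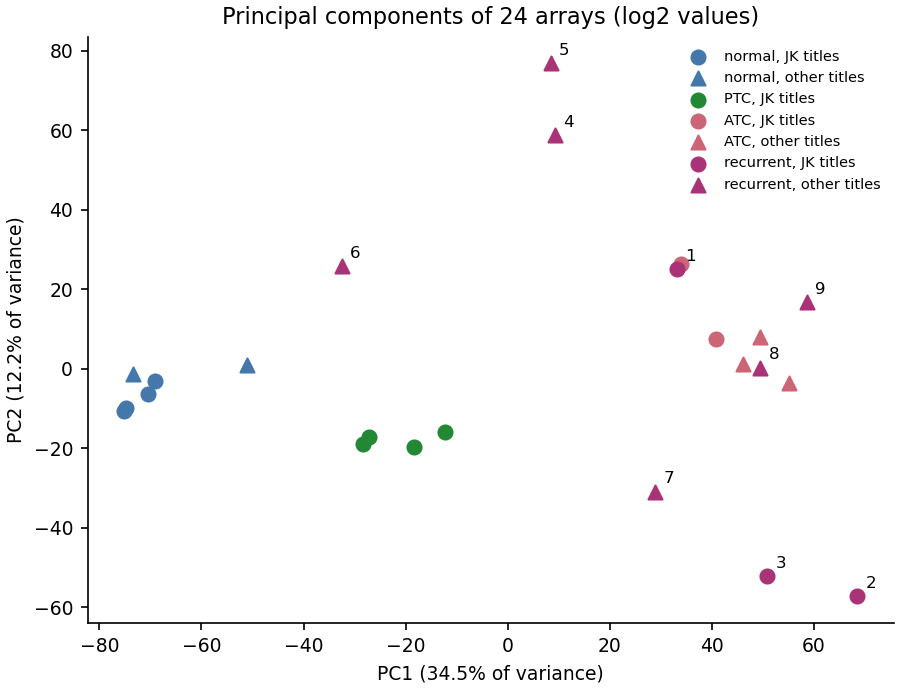
First and second principal components of the 24 arrays (34.5% and 12.2% of the variance), with colour for the group, circles for JK titles, triangles for other titles, and numbers for the recurrent replicates. Normal pools sit at the left, PTC between them and ATC, and the 9 recurrent arrays are spread over both axes.

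Braf, the gene whose product the study inactivates, was read first on every array. Its level was 6.25 ± 0.29 (log2, SD, n = 6) in normal pools, 7.78 ± 0.15 (SD, n = 4) in PTC, 11.31 ± 0.72 (SD, n = 5) in ATC and 6.74 ± 1.74 (SD, n = 9) in recurrent tumours. Of the 9 recurrent arrays, 8 lay between 5.62 and 7.14, below every ATC array, and the array labelled recurrent 2 lay at 11.14, within the ATC range of 10.29 to 11.98. ATC exceeded normal by 5.06 (limma adjusted p = 5.26e-06), and recurrent tumours fell by 4.57 from ATC (limma adjusted p = 7.28e-05). The second difference was -3.81 within the JK series, where array 2 is 1 of 3 recurrent arrays, with limma adjusted p = 0.0559. PTC exceeded normal by 1.53, which limma did not call (adjusted p = 0.169) but did in a fit of the 10 arrays alone (limma adjusted p = 1.45e-05). All 4 PTC arrays lay above all 6 pools (two-sided exact permutation p = 0.00952, and 0.00952 after adjustment over 4 such tests added after the values were seen). Whether the probe set reads transcripts of an engineered allele is not given in the sources used here.

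**Figure D2:**
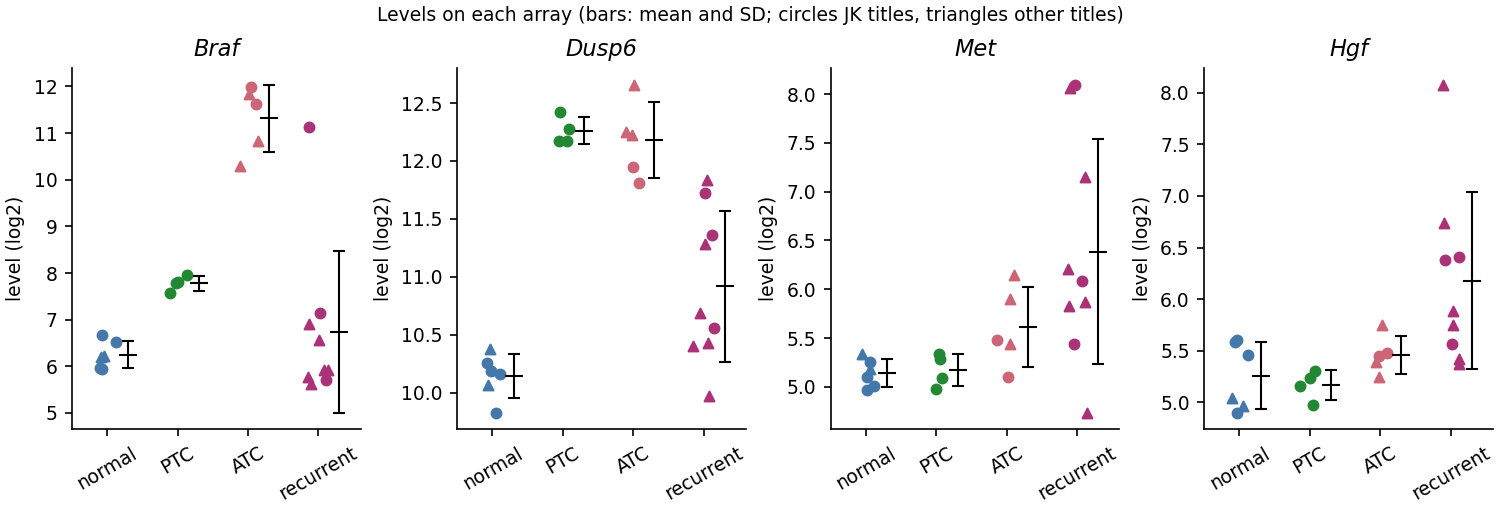
Log2 levels of Braf, Dusp6, Met and Hgf on each array, by group, with the mean and SD beside the points, circles for JK titles and triangles for other titles. Braf is at 10.29 to 11.98 in ATC and at 5.62 to 7.14 on 8 of the 9 recurrent arrays, and Met reaches 8.10 and 8.06 on recurrent arrays 1 and 8.

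The PTC comparison asks what distinguishes papillary tumours from normal glands. PTC carried very high levels of some surfactant protein genes, which are best known from the lung lining. A further one, Sftpc, looked up after the results were seen, was at 6.43 in PTC against 6.42 in normal pools. Sftpa1 was 14.39 ± 0.09 (log2, SD, n = 4) against 5.27 ± 0.98 (SD, n = 6) in normal pools, Sftpd was higher by 7.94 and Sftpb by 6.75. Gzme and Mcpt8, which encode proteases of granule-bearing immune cells, rose by 8.75 and 7.01. Rises were also seen in Chil1, a chitinase-like secreted protein (7.75), Dlk1, an inhibitor of cell differentiation (7.72), and Ereg, a ligand of the EGF receptor (6.94). Falls were led by Grp, gastrin-releasing peptide, by -7.98, chromogranin A of neuroendocrine cells, Chga, by -6.26, Dio1, a deiodinase that makes active thyroid hormone, by -5.80, the neuroendocrine Scg2 by -5.70, the brown fat protein Ucp1 by -5.34 and the FGF23 co-receptor Kl by -4.81. Sftpc apart, limma adjusted p-values of these 14 genes ran up to 0.0125, that of Chga. It was not called without PTC array 1 (limma adjusted p = 0.0525).

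In the thyroid differentiation list, 6 of 15 measured members fell and 1 rose (7 and 1 adjusted over the list alone). Besides Dio1, they included the anion transporter Slc5a8 (-3.74), the thyrotropin receptor Tshr (-1.75) and the iodide transporter Slc5a5 (-0.67, limma adjusted p = 0.00379). Thyroglobulin, Tg, was 13.57 ± 0.48 (SD, n = 4) against 14.88 ± 0.06 (SD, n = 6), and limma did not call it (adjusted p = 0.725). All 4 PTC arrays lay below all 6 pools and a fit of the 10 arrays alone called it (limma adjusted p = 0.000121). Of 20 measured MAPK output genes, 9 rose and 0 fell (11 and 0 adjusted over the list alone), among them the ERK phosphatase Dusp6 (2.12), the transcription factor Etv4 (2.46) and cyclin D1, Ccnd1 (3.41). Mitosis and replication genes rose in 13 of 27 cases with 0 falls (21 and 0 adjusted over the list alone), with Birc5 at 2.25, Cdc20 at 2.05 and the proliferation marker Mki67 at 2.23. Normal pools 3 and 5 had higher means of this list (0.52 and 0.64) than the other pools (-0.35 to -0.16), with PTC at 1.03 to 1.70. The Mki67 level of pool 5 (8.56) was above the lowest PTC array (8.46). Birc5 and Mki67 were not called without PTC array 1 (limma adjusted p = 0.0601 and 0.0629) or without PTC array 4 (0.0727 and 0.0663). limma camera adjusted p-values were 0.00166, 1.1e-07 and 2.49e-10 for these 3 lists in turn, and adjusted p = 0.318, 0.224 and 0.318 with an estimated correlation.

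Matrix and mesenchymal genes moved upward in part. The fibroblast and matrix list had 3 of 22 members up and 0 down (3 and 0 adjusted over the list alone), including collagen Col1a1 (2.64). The mesenchymal list had 5 of 19 up and 0 down (9 and 0 adjusted over the list alone), including fibronectin, Fn1 (2.57). TGF-beta pathway genes had 2 of 12 up and 0 down (6 and 0 adjusted over the list alone), with the secreted Tgfbi at 3.22. The macrophage list had 2 of 21 up and 0 down (1 and 0 adjusted over the list alone), with the scavenger receptor Marco at 2.20. Normal pool 5, with a macrophage list mean of 1.12, lay within the PTC range of 0.67 to 1.65, and the other pools at -0.47 to -0.05. limma camera gave adjusted p = 0.00222, 0.000602, 0.000537 and 0.000116 for the 4 lists, and adjusted p = 0.559, 0.46, 0.318 and 0.46 with an estimated correlation. Endothelial genes went down in 6 of 18 cases and up in 0 (6 and 0 adjusted over the list alone), such as Emcn (-1.85) and the VEGF receptor Kdr (-1.31). Adipocyte genes went down in 8 of 10 cases (10 adjusted over the list alone), parathyroid genes in 2 of 4 (4 adjusted over the list alone) and C-cell genes in 4 of 7 with 1 rise (4 and 1 adjusted over the list alone). Normal pool 5 stood apart from the other pools in the adipocyte list mean (-2.10 against 0.28 to 0.54) and the C-cell mean (-1.42 against 0.11 to 0.51). For these 4 lists limma camera gave adjusted p = 0.000237, 8.67e-09, 0.00542 and 0.0071, and adjusted p = 0.318, 0.224, 0.318 and 0.318 with an estimated correlation. Met differed by 0.03 ± 0.47 (SE) and Hgf by -0.09 ± 0.36 (SE), neither called by limma (adjusted p = 0.984 and 0.936).

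Other probe sets gave smaller changes for Kl (-0.21), Tshr (-0.06) and Cdc20 (0.58 and 1.53). limma called 1758 of 12394 genes between PTC and normal, 763 higher and 995 lower. The groups did not overlap in 34.3% of genes, where chance gives 0.952%. The count became 5676 in a fit of the 10 arrays alone, 6370 with array weights and 3156 within the JK series, and it was 1660 with the title series as a block.

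The comparison of ATC with normal glands asks what anaplastic tumours lose and gain. Prkg2, a cyclic GMP-dependent kinase, was 13.04 ± 0.30 (log2, SD, n = 5) against 4.22 ± 0.41 (SD, n = 6). The macrophage product Chil3 rose by 8.11, keratin Krt20 by 7.10, arginase Arg1 by 6.71, collagenase Mmp13 by 6.59 and the protease inhibitor Timp1 by 6.42. Grp fell by 7.96, Tg by 7.94, Dio1 by 7.38, the iodotyrosine deiodinase Iyd by 7.27 and the bicarbonate transporter Slc4a5 by 6.65, all with limma adjusted p up to 0.000491. ATC array 4 stood apart in Tg, at 13.48. Parathyroid hormone, Pth, fell by 6.69 with a spread of 4.56 (SD, n = 5) between ATC arrays, and was not called within the JK series (-1.80, limma adjusted p = 0.375), outside it (0.121), with bare-number titles as a block (0.0618) or without ATC array 3 or 4 (0.0563 and 0.0534).

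Of the thyroid differentiation genes, 10 of 15 fell and 0 rose (10 and 0 adjusted over the list alone), including Slc5a5 at -0.77, which the JK arrays alone put at -0.47 (limma adjusted p = 0.0937). MAPK output genes rose in 13 of 20 cases and fell in 1 (14 and 1 adjusted over the list alone), among them the cytokine Lif (3.89), the early response gene Ier3 (3.75), the AP-1 subunit Fosl1 (3.50) and Dusp6 (2.03). Mitosis and replication genes rose in 25 of 27 cases (26 adjusted over the list alone), for example Birc5 (3.87), Bub1 (3.77), Rrm2 (3.51) and Mki67 (3.08). limma camera adjusted p-values were 1.34e-06, 6.83e-08 and 5.16e-15 in that order, and adjusted p = 0.11, 0.186 and 0.214 with an estimated correlation.

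Fibroblast and matrix genes rose in 15 of 22 cases (15 adjusted over the list alone), with Col1a1 up by 4.87, and mesenchymal genes in 14 of 19 (14 adjusted over the list alone), with the collagen cross-linking enzyme Lox up by 4.28 and Fn1 by 4.02. The TGF-beta list had 10 of 12 members up (10 adjusted over the list alone), led by the activin subunit Inhba (4.47). Macrophage genes rose in 17 of 21 cases (17 adjusted over the list alone), such as Mrc1 (3.13) and Msr1 (3.05), and neutrophil genes in 5 of 11 (5 adjusted over the list alone), such as the calcium-binding S100a8 (4.89). These 5 lists had limma camera adjusted p = 3.01e-08, 2.48e-08, 1.34e-06, 6.83e-08 and 0.0116, and adjusted p = 0.275, 0.238, 0.186, 0.352 and 0.37 with an estimated correlation. All 10 measured adipocyte genes fell (10 adjusted over the list alone), with Adipoq at -5.42 and Ucp1 at -5.92, and C-cell genes fell in 4 of 7 cases and rose in 1 (5 and 1 adjusted over the list alone). limma camera adjusted p was 5.11e-07 and 0.0195 for the last 2 lists, and adjusted p = 0.186 and 0.365 with an estimated correlation. Met was higher by 0.47 ± 0.44 (SE) and Hgf by 0.20 ± 0.34 (SE), neither called (limma adjusted p = 0.44 and 0.687). Met was called in a fit of the 11 arrays alone (limma adjusted p = 0.0342) and with array weights (0.65, limma adjusted p = 0.0442).

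Other probe sets gave smaller changes for Prkg2 (4.06), Lif (0.46), Fosl1 (1.20), Bub1 (0.65), and for 1 of 2 more in Rrm2 (1.78) and Lox (0.79), and for Msr1 1.83 to 2.28. Between ATC and normal, limma called 4245 of 12394 genes, 1877 higher and 2368 lower, and 34.1% of genes did not overlap, against 0.433% by chance. Array weights raised the count to 7357, and the 5 arrays outside the JK series gave 759 (where 15 of 31 called genes followed were not called), against 3921 within it and 4413 with the series as a block.

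**Figure D3:**
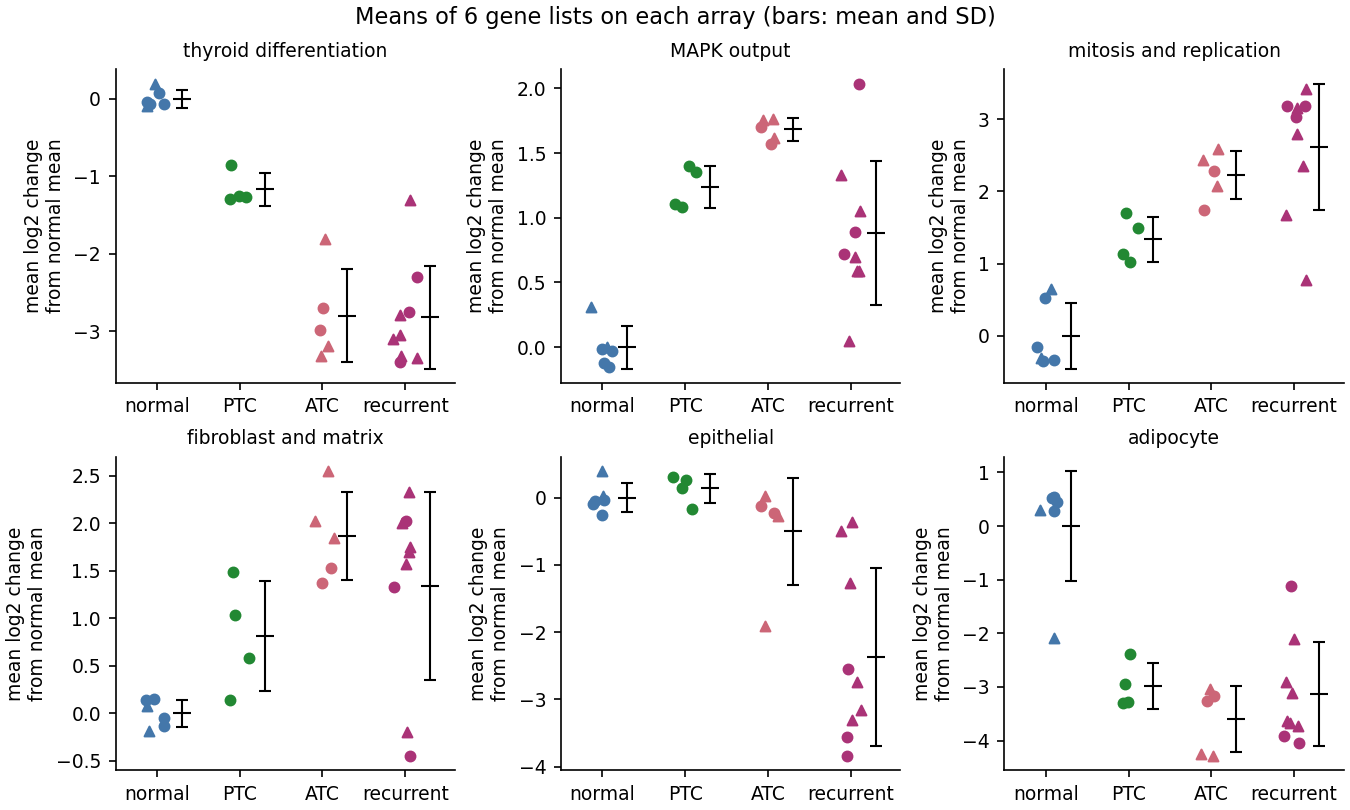
Mean log2 change from the normal mean over the members of 6 gene lists on each array, by group, with mean and SD beside the points, circles for JK titles and triangles for other titles. The MAPK output mean is 1.57 to 1.77 in ATC and 0.05 to 2.04 in recurrent tumours, and the epithelial mean falls to -3.84 on a recurrent array.

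The comparison of the 2 tumour types asks what separates ATC from PTC. Sox2, a transcription factor of stem and airway cells, was 10.40 ± 0.84 (log2, SD, n = 5) in ATC against 3.83 ± 0.11 (SD, n = 4) in PTC. The surface protein Msln (5.47), Prkg2 (5.19), the stress keratin Krt6a (4.92) and the myeloid protease Adamdec1 (4.86) were also higher in ATC. Lower in ATC were Sftpa1 (-8.71), Dlk1 (-7.13), Sftpd (-6.91), Tg (-6.63), Sftpb (-5.89) and Iyd (-4.62), as well as Pax8 (-3.49), the transcription factor of thyroid identity. limma adjusted p-values of these 12 genes ran up to 0.0112. Braf was higher by 3.54 (limma adjusted p = 0.00188).

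Thyroid differentiation genes were lower in ATC in 6 of 15 cases and higher in 0 (7 and 0 adjusted over the list alone). Fibroblast and matrix genes were higher in 6 of 22 (6 adjusted over the list alone), including the matrix protein Fbln2 (2.60) and Col1a1 (2.23), the latter not called within the JK series (1.82, limma adjusted p = 0.143), without PTC array 2 or 3 (0.0577 and 0.0735) or with bare-number titles as a block (0.0594). The mesenchymal list had 5 of 19 members higher (7 adjusted over the list alone), the TGF-beta list 4 of 12 (4 adjusted over the list alone), among them Inhba (2.91) and Tgfb1 (1.71), and the mitosis list 4 of 27 (4 adjusted over the list alone). In the macrophage list 2 of 21 were higher, including the integrin Itgam (2.14), and 1 was lower (2 and 1 adjusted over the list alone). With bare-number titles as a block Itgam was at 1.83 and not called (limma adjusted p = 0.0659). limma camera gave these 6 lists adjusted p = 0.000829, 0.000131, 0.000303, 0.00796, 0.000137 and 0.00796, and adjusted p = 0.613, 0.789, 0.789, 0.789, 0.789 and 0.789 with an estimated correlation. With the title series as a block the TGF-beta and macrophage lists were not called (limma camera adjusted p = 0.056 for both). Of the genes around Met, the urokinase Plau, which can activate Hgf, was higher by 3.69 and the Hgf activator Hgfac by 2.78, while 3 of 11 members of the Hgf and Met list were higher and 3 lower (3 and 3 adjusted over the list alone; limma camera adjusted p = 0.731, and adjusted p = 0.831 with an estimated correlation). Dusp6 differed by -0.08 ± 0.29 (SE), Mki67 by 0.85 ± 0.65, Slc5a5 by -0.10 ± 0.16, Met by 0.44 ± 0.49 and Hgf by 0.29 ± 0.37, none of them called (lowest limma adjusted p = 0.413). Mki67 was called in a fit of the 9 arrays alone (limma adjusted p = 0.0267).

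Other probe sets gave smaller changes for Krt6a (2.67 and 1.92), Plau (2.10) and Prkg2 (3.91). limma called 2127 genes between ATC and PTC, 968 higher and 1159 lower, with 32.5% of genes not overlapping against 1.59% by chance. The count was 4587 in a fit of the 9 arrays alone, 6318 with array weights and 1345 without PTC array 2, and within the JK series, which alone holds PTC, it was 1960.

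Recurrent tumours were set against ATC, the group the series title takes as their origin. The immune cell granule proteases Gzme (-6.08), Mcpt8 (-5.85) and Gzmd (-5.22) fell. So did neuropeptide Npy (-5.92), Adamdec1 (-5.42), the retinoic acid synthesis enzyme Aldh1a3 (-5.10) and keratin Krt7 (-4.66). Npy was 7.02 ± 1.07 (log2, SD, n = 9) against 12.94 ± 0.69 (SD, n = 5). Fewer genes rose by as much. They were led by Crabp1, a retinoic acid binding protein (4.51), followed by the axon guidance ligand Ntn1 (2.25) and the kinase Lrrk2 (1.85), and limma adjusted p of these 10 genes ran up to 0.00874. The 3 rises were not called in a fit of the 14 arrays alone (limma adjusted p = 0.0811, 0.08 and 0.116).

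MAPK output genes fell in 5 of 20 cases and rose in 0 (9 and 0 adjusted over the list alone). The list mean was lower than on every ATC array (1.57 to 1.77) on 8 of the 9 recurrent arrays, and above them on the array labelled recurrent 2 (2.04). Lif fell by 2.21, Etv4 by 1.43, Ccnd1 by 1.33 and Dusp6 by 1.26 (highest limma adjusted p = 0.00999), and the last 3 were not called in a fit of the 14 arrays alone (limma adjusted p = 0.0991, 0.0775 and 0.0786). Within the JK series Dusp6 differed by -0.66 and Etv4 by -0.68, with limma adjusted p = 0.17 and 0.178. Against normal glands Dusp6 was higher in recurrent tumours by 0.77 (limma adjusted p = 0.0127). Recurrent array 6 lay within the normal range (9.97), and Dusp6 was not called outside the JK series (0.55, limma adjusted p = 0.515). Epithelial genes fell in 7 of 19 cases (12 adjusted over the list alone), such as Krt19 (-3.72). The list mean was within the ATC range (-1.91 to 0.02) on recurrent arrays 4, 5 and 6 (-1.27, -0.49 and -0.36) and below it on the other 6. Krt19 was not called in a fit of the 14 arrays alone (limma adjusted p = 0.15). The TGF-beta list had 4 of 12 members down (7 adjusted over the list alone), including Inhba (-2.13) and Tgfb1 (-1.53), and these were -0.54 and -0.99 within the JK series (limma adjusted p = 0.447 and 0.112). limma camera adjusted p was 3.35e-08, 3.6e-10 and 7.23e-06 for the 3 lists, and adjusted p = 0.115, 0.131 and 0.131 with an estimated correlation.

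In the Hgf and Met list, 3 of 11 members fell and 0 rose (5 and 0 adjusted over the list alone), namely Plau (-3.01), its receptor Plaur (-2.11) and Hgfac (-2.81). Plaur was not called in a fit of the 14 arrays alone (limma adjusted p = 0.146), within the JK series (0.202), outside it (0.24) or without ATC array 3 or 5 (0.0582 and 0.0551). Receptor tyrosine kinases and their ligands fell in 5 of 32 cases (6 adjusted over the list alone), with the EGF receptor ligands Hbegf (-1.96) and Tgfa (-1.82), neither called in a fit of the 14 arrays alone (limma adjusted p = 0.141 and 0.0991). Fibroblast and matrix genes fell in 2 of 22 (5 adjusted over the list alone), including Tagln (-1.59; not called in a fit of the 14 arrays alone, limma adjusted p = 0.119), endothelial genes in 1 of 18 (1 adjusted over the list alone), macrophage genes in 0 of 21 (0 adjusted over the list alone), and mitosis genes rose in 0 of 27 (0 adjusted over the list alone), although limma camera called all 4 lists. These 6 lists had limma camera adjusted p = 0.00106, 0.00436, 0.00136, 0.00123, 0.00153 and 0.0121, and adjusted p = 0.067, 0.115, 0.813, 0.626, 0.849 and 0.873 with an estimated correlation. Mean changes of the fibroblast and matrix list from normal were -0.45 and -0.19 on recurrent arrays 2 and 6 and 1.33 to 2.33 on the other 7, against 1.37 to 2.55 in ATC. Without normal 5 and recurrent 2, 3 and 6, chosen after seeing the data, that list turned in direction (limma camera adjusted p = 0.908), and the receptor tyrosine kinase, endothelial and macrophage lists were not called (0.137, 0.108 and 0.339). The means of the skeletal muscle list, which reads muscle as may lie beside the gland, ranged from -4.98 to 3.35 over the recurrent arrays and from -2.43 to 1.44 in ATC. Mki67 differed by 0.38 ± 0.54 (SE), Tg by -0.23 ± 1.46 and Slc5a5 by 0.08 ± 0.13, none called by limma (lowest adjusted p = 0.763).

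Met was 6.39 ± 1.15 (log2, SD, n = 9) in recurrent tumours and 5.61 ± 0.41 (SD, n = 5) in ATC, and Hgf was 6.18 ± 0.86 against 5.46 ± 0.18. The differences of 0.77 ± 0.40 and 0.72 ± 0.31 (SE) were not called by limma (adjusted p = 0.331 and 0.213). Two-sided exact permutation tests of the same groups gave p = 0.19 for Met and 0.04 for Hgf, or 0.19 and 0.0799 after adjustment over the 2 tests. Met exceeded all ATC arrays on 4 of 9 recurrent arrays and Hgf on 5, and Met was highest on arrays 1 (8.10) and 8 (8.06) and next on array 6 (7.15). Hgf was highest on array 8 (8.08), followed by arrays 4 (6.73), 1 (6.41) and 2 (6.38). Within the JK series the differences were 1.25 and 0.66, and outside it 0.48 and 0.75 (lowest limma adjusted p = 0.166). With array weights Hgf was higher by 1.06 and called (limma adjusted p = 0.0225).

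Across the 9 recurrent arrays Met and Hgf had a Pearson r of 0.583 (exact permutation p = 0.0957) and a Spearman rho of 0.517 (exact permutation p = 0.162). Without arrays 1 and 8, the farthest from the median of Met, r was -0.00361 (exact permutation p = 0.993), so the relation rests on those arrays. It was 0.278 without array 8 alone (exact permutation p = 0.51) and 0.636 without array 1 alone (exact permutation p = 0.103). Met and the mean of 11 other genes near it on its chromosome had r = 0.6252 (exact permutation p = 0.072) and rho = 0.533 (exact permutation p = 0.148), and r was -0.03 without arrays 1 and 8 (exact permutation p = 0.957). After adjustment over the 4 coefficients all were at 0.162. Without array 6 the second relation had r = 0.927 (exact permutation p = 0.00141) and the first r = 0.728 (exact permutation p = 0.0415). Among the 6 arrays outside the JK series the 2 values of r were 0.704 and 0.481, and the 3 JK arrays are too few for one.

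**Figure D4:**
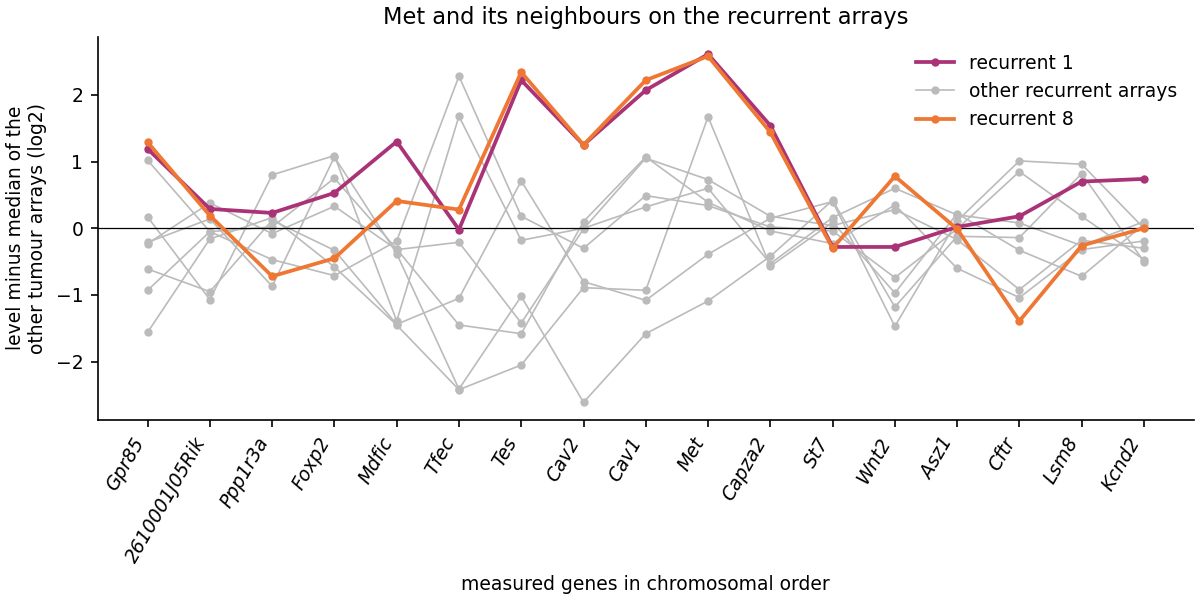
Log2 level of each measured gene minus the median of the other tumour arrays, for Met and 16 neighbours in chromosomal order, on the 9 recurrent arrays. On arrays 1 and 8 the run from Tes to Capza2 lies at 1.25 or more, and St7, the next gene, lies at -0.28 and -0.30. On the other side the edge is less sharp. Tfec lies at -0.02 and 0.28, Mdfic at 1.30 and 0.41 and Gpr85 at 1.19 and 1.29. Tes, Cav2, Cav1, Capza2, St7, Tfec, Mdfic and Gpr85 were chosen after their values were seen.

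Other probe sets gave smaller changes for Ntn1 (0.57), Lif (-0.30), Tgfa (-0.09 and -0.16), Plau (-1.62) and Aldh1a3 (-2.87 and -4.01). limma called 535 genes between recurrent tumours and ATC, 148 higher and 387 lower, and 0.888% of genes did not overlap against 0.0999% by chance. Only 99 were called (7 higher and 92 lower) in a fit of these 14 arrays alone. On simulated data for this comparison, with 200 changed genes, 16.8% of the calls were unchanged genes. The share among the 535 real calls was not estimated. The count ranged from 286 to 844 when single arrays were left out, with 335, 298, 286 and 302 without ATC arrays 1, 2, 3 and 5 and 844 without the array labelled recurrent 2, and it was 933 within the JK series and 41 outside it. Of 25 called genes followed through the alternatives, 13 were not called in the fit of the 14 arrays, 10 within the JK series and 18 outside it.

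The last comparison sets recurrent tumours against normal glands. Tg was 6.71 ± 3.52 (log2, SD, n = 9) against 14.88 ± 0.06 (SD, n = 6). Recurrent arrays 4 and 1 stood apart at 14.18 and 11.31 and the other 7 at 4.61 to 5.86. Pth, Iyd, Grp and Dio1 had log2 changes of -8.04, -7.61, -7.56 and -7.20. Prkg2 rose by 5.31, Timp1 by 5.21, Arg1 by 5.02, Mmp13 by 5.01, Sox2 by 4.69 and Crabp1 by 4.40, and limma adjusted p of these 11 genes ran up to 0.00174. Met was higher by 1.25 (limma adjusted p = 0.0143) and Hgf by 0.92 (limma adjusted p = 0.0175), on 8 and 6 of the 9 recurrent arrays above every normal pool. Two-sided exact permutation tests, added after the values were seen, gave p = 0.00759 and 0.00879 (0.00952 each after adjustment over the 4 added tests). Neither was called in a fit of the 15 arrays alone (limma adjusted p = 0.0526 and 0.0656) or among arrays outside the JK series (1.05 and 1.21, limma adjusted p = 0.447 and 0.323), nor with bare-number titles as a block (1.21 and 0.89, limma adjusted p = 0.054 and 0.0639). Hgf was 0.79 with the 4 pools titled WT alone (limma adjusted p = 0.0938), and Braf differed by 0.49 ± 0.58 (SE) and was not called (limma adjusted p = 0.553). Without the array labelled recurrent 2 it differed by -0.06.

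Mitosis and replication genes rose in 26 of 27 cases (26 adjusted over the list alone), for example Rrm2 (4.23), Birc5 (4.13), Bub1 (3.81) and Mki67 (3.47). MAPK output genes rose in 11 of 20 and fell in 1 (11 and 3 adjusted over the list alone), with Ier3 (2.33) and Myc (2.26). Thyroid differentiation genes fell in 10 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone), including Slc5a5 (-0.69). Epithelial genes fell in 15 of 19 (16 adjusted over the list alone), with Epcam (-3.14) and the tight junction gene Cldn7 (-3.51), which were not called outside the JK series (limma adjusted p = 0.413 and 0.386). Epcam on recurrent array 6 (13.26) was above every normal pool. limma camera adjusted p was 1.98e-21, 0.00102, 8.34e-07 and 6.61e-06 for the 4 lists, and adjusted p = 0.223, 0.358, 0.0802 and 0.358 with an estimated correlation. Spint2, an inhibitor of the proteases that activate Hgf, and St14, an epithelial surface protease, fell too (-2.82 and -2.60), within a list of 11 in which 3 rose and 4 fell (3 and 4 adjusted over the list alone; limma camera adjusted p = 0.863, and adjusted p = 0.898 with an estimated correlation).

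Mesenchymal genes rose in 15 of 19 cases (15 adjusted over the list alone), such as Lox (3.61) and Fn1 (3.03), fibroblast and matrix genes in 11 of 22 (13 up and 1 down adjusted over the list alone), such as Col1a1 (4.22), and TGF-beta genes in 6 of 12 (7 up and 1 down adjusted over the list alone). Macrophage genes rose in 9 of 21 (13 adjusted over the list alone), including Itgam (2.54) and Msr1 (2.41). Recurrent arrays 2, 6 and 7 lay within or below the normal range of that list mean (-0.07, -0.94 and 0.36), the other 6 at 1.40 to 2.53, and array 6 was at -0.49 in the mesenchymal mean. Neutrophil genes rose in 4 of 11 (4 adjusted over the list alone), including S100a8 (3.58). The neutrophil mean was highest on recurrent array 2 (3.67) and within the normal range (-0.27 to 0.46) on array 7 (-0.18). On the rest it ran from 0.58 to 2.42. limma camera adjusted p was 1.35e-08, 6.61e-06, 0.00241, 2.28e-05 and 0.0036, and adjusted p = 0.268, 0.358, 0.358, 0.383 and 0.358 with an estimated correlation. Endothelial genes fell in 10 of 18 (10 adjusted over the list alone), with Kdr at -2.00 and Emcn at -1.57, interferon and antigen presentation genes in 6 of 18 (6 adjusted over the list alone), adipocyte genes in 9 of 10 (10 adjusted over the list alone), with Adipoq at -4.73, parathyroid genes in 3 of 4 (4 adjusted over the list alone) and C-cell genes in 5 of 7 (5 down and 1 up adjusted over the list alone). The parathyroid mean was near normal on recurrent arrays 4 and 5 (0.64 and -0.25) and between -5.73 and -4.70 on the other 7. limma camera adjusted p was 0.00202, 0.0308, 5.73e-07, 0.0308 and 0.00125, and adjusted p = 0.383, 0.619, 0.225, 0.383 and 0.268 with an estimated correlation. Without normal 5 and recurrent 2, 3 and 6 the endothelial, interferon and parathyroid lists were not called (limma camera adjusted p = 0.0766, 0.985 and 0.229).

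Other probe sets gave smaller changes for Prkg2 (1.05), Bub1 (0.79), Lox (0.34, and 3.48 for another) and Msr1 (1.25 to 1.73). Between recurrent tumours and normal glands limma called 4194 genes, 1802 higher and 2392 lower, and 8.02% of genes did not overlap against 0.04% by chance. Simulated data for this comparison, with 200 changed genes, had 13.3% unchanged genes among the calls. The share among the 4194 real calls was not estimated. The count was 503 outside the JK series (where 25 of 35 called genes followed were not called), 5150 within it and 4320 with the series as a block. In no comparison did limma camera call the lists of T and NK cells, B and plasma cells, skeletal muscle, trachea and cartilage, Met neighbours, p53 targets, or hypoxia and glycolysis, whose lowest adjusted p was 0.218, 0.344, 0.231, 0.11, 0.22, 0.135 and 0.0593 in turn.

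**Figure D5:**
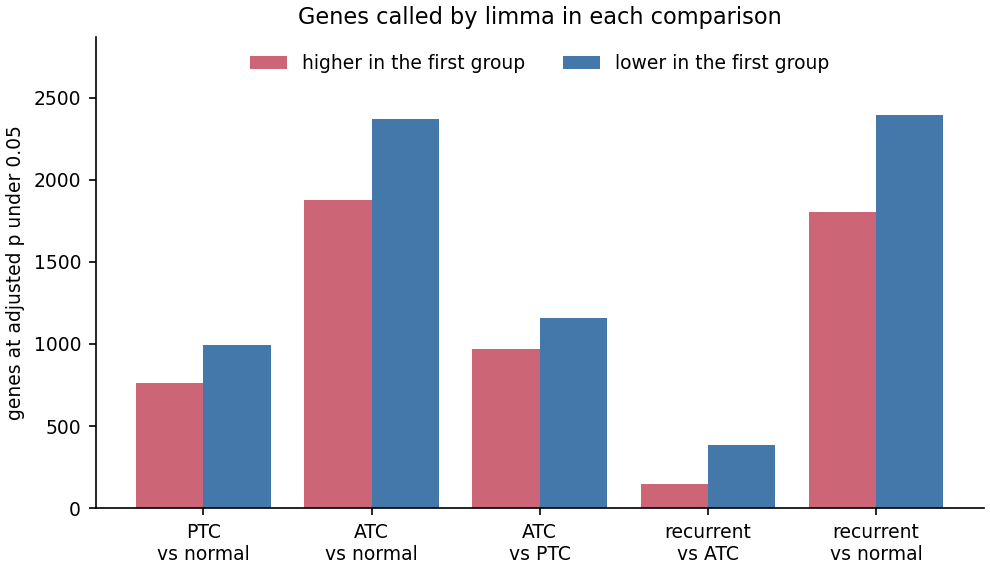
Number of genes called by limma at adjusted p under 0.05 in each of the 5 comparisons, higher (red) and lower (blue) in the first group, on an axis from 0. The lowest total is the 535 genes of recurrent tumours against ATC.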

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

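All tests in this part were chosen only after the results were seen. A value stands here when, in a group of 4 to 9 arrays, its gap to the nearest other array is a large share of the whole range (above Dixon's 95% critical value). Of 229 groups of values tested 28 were beyond it, where chance alone brings out about 1 in 20. Levels are log2.

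Normal pool 6, titled Cre unlike the WT pools, held no such value. Normal pool 5, also titled Cre, held the largest number of them. It was high in Chil3 (6.19), Ereg (7.20), Inhba (8.11), Mmp13 (6.72), Msr1 (8.50), Sftpa1 (7.18), Sftpd (9.32), St14 (10.61), Tgfbi (11.71) and Timp1 (8.93), and low in Scg2 (8.10) and the brown fat gene Ucp1 (5.60). Normal pool 2 was high in Marco (5.67). PTC array 2 was low in Prkg2 (6.78).

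ATC array 4 was high in thyroid transcripts, with Tg at 13.48 (other ATC arrays 4.46 to 5.98), Iyd at 9.99 (4.56 to 5.52) and Dio1 at 7.90 (4.30 to 4.58). It was also high in Slc4a5 (7.07) and Msr1 (10.07), and low in Krt19 (8.47) and Msln (8.58). ATC array 3 was high in Sftpa1 (8.92). Recurrent array 4 was high in Dio1 (9.38) and Grp (9.47), array 9 in Gzmd (5.94) and array 8 in Hgf (8.08), and array 6 was low in Sox2 (3.65).

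Met stood high on recurrent arrays 1 and 8 together with the genes next to it, Tes, Cav2, Cav1 and Capza2, chosen after their values were seen. On those arrays each of the 5 genes was 1.25 or more above the median of the other tumours. Medians of all genes there lay at most 0.034 from the other tumours, but RMA brings array medians together. They therefore cannot test scaling of the whole array. The mean of the 5 genes lay 4.54 and 4.49 residual SDs above the level predicted from the fibroblast and matrix list on arrays 1 and 8. That line was nearly flat (10.05 and 10.1 predicted from list means of 11.78 and 12.08). Its excess therefore cannot test for more stroma. Both list means lay within the range of the other 12 ATC and recurrent arrays (9.3 to 12.3). From the endothelial list the mean of the 5 genes lay 8.65 and 6.55 above, which argues against more vessels. From the adipocyte list it lay 4.36 and 4.59 above. That line was also nearly flat (10.03 and 9.95 predicted), so more fat is not settled. The adipocyte mean was outside the range behind the prediction (5.91 to 8.1) on array 1 (9.07) and within it on array 8 (6.53). A run this high came up in 1 of 2000 shuffled gene orders, which argues against chance order. A gain of DNA around Met may be a candidate explanation, but no biological explanation was tested, since DNA was not analysed here, and the pattern was found and tested on the same arrays.

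Braf on the array labelled recurrent 2 was 11.14, where the other recurrent arrays lay at 5.62 to 7.14. An ATC array under a wrong label is argued against by 118 other genes that separate the groups, which put this array at 0.19 on a scale from 0 (mean of the other recurrent arrays) to 1 (ATC mean), with ATC arrays at 0.91 to 1.09 and the other recurrent arrays at -0.24 to 0.26. The median deviation over all genes was 0.06, but RMA holds it near 0, so it cannot test scaling. A tumour with BRAF still expressed, or another swap of samples, could give such a level and stays open, and no biological explanation was tested.

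Sftpa1, Sftpb and Sftpd were high on all PTC arrays. Lung tissue in the samples is argued against by 9 other measured lung markers, with a median PTC minus normal difference of -0.56 and 1 of them higher by over 1. Sftpc, 1 of the 9, was at 6.43 in PTC against 6.42 in normal pools. The median difference of all genes was -0.01, which cannot test scaling because RMA brings array medians together. Expression of these genes by the tumour cells may remain as a hypothesis, and no biological explanation was tested.

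Random splits of the same arrays, 100 per comparison with the real one included, tested whether chance could give as many calls. For genes, only the real split reached the real count in 4 comparisons. These were PTC against normal (1758, highest other 55), ATC against normal (4245, highest other 3338), ATC against PTC (2127, highest other 815) and recurrent against normal (4194, highest other 2659). For these 4 counts a chance division of arrays taken as independent is argued against at the level of 1 in 100 splits. Labels do not say that the tumours came from separate animals, and a difference that follows the titles is not excluded. For recurrent against ATC 3 splits, the real one included, reached the real count (535, highest other 1087). The splits did not keep the titles together, so they cannot settle whether chance gave this count. A split that calls 1087 genes points to a structure among the recurrent and ATC samples other than the groups. With terms for the titles, 2227 genes differed between bare-number titles and all others and 1223 between JK and other titles. For lists, as many were called in 22 splits for PTC against normal (11, highest other 15), 52 for ATC against normal (10, highest other 15), 66 for ATC against PTC (6, highest other 11), 36 for recurrent against ATC (9, highest other 14) and 8 for recurrent against normal (14, highest other 16), so chance cannot be excluded for the numbers of lists.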

How the results depend on the processing

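The alternatives by bare-number titles, the omission of normal 5 and recurrent 2, 3 and 6, and the correlations over the 6 arrays outside the JK series were chosen after seeing the data. Of 3896 values for 155 gene results, 3750 kept their direction and side of the threshold, 115 lost the call, 7 gained it, and 24 changed sign where neither value was called, such as Tg between recurrent and ATC (-1.39 to 1.65), while 0 called values changed sign. Genes called were 1758 for PTC against normal (PTC/N), 4245 for ATC against normal (ATC/N), 2127 for ATC against PTC (ATC/PTC), 535 for recurrent against ATC (rec/ATC) and 4194 for recurrent against normal (rec/N). Counts beyond 1.5 times these follow by setting. A fit of the 2 groups alone gave 5676 (PTC/N), 4587 (ATC/PTC) and 99 (rec/ATC), and array weights gave 6370 (PTC/N), 7357 (ATC/N), 6318 (ATC/PTC) and 1360 (rec/ATC). The JK series alone gave 3156 (PTC/N) and 933 (rec/ATC), and arrays outside it gave 759 (ATC/N), 41 (rec/ATC) and 503 (rec/N). Every probe set on its own gave 2675 (PTC/N), 7125 (ATC/N), 3891 (ATC/PTC) and 7274 (rec/N), since more features are tested. A 2-fold minimum gave 1007 (PTC/N), 2325 (ATC/N), 1156 (ATC/PTC), 296 (rec/ATC) and 1947 (rec/N). Without bare-number titles the counts were 3433 (PTC/N) and 1065 (rec/ATC), and without normal 5 and recurrent 2, 3 and 6 they were 3300 (PTC/N), 3847 (ATC/PTC) and 1592 (rec/ATC). Leaving out single arrays gave 1182 to 1768 (PTC/N), 3586 to 4102 (ATC/N), 1345 (without PTC 2) to 2115 (ATC/PTC), 286 (without ATC 3) to 844 (without recurrent 2) in rec/ATC, and 3578 to 4849 (rec/N). Without ATC 1, 2 and 5 rec/ATC was 335, 298 and 302.

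With an estimated correlation the number of lists called was 0, 0, 0, 0 and 0, and of 115 list results 50 lost the call. The fibroblast and matrix list changed direction between recurrent and ATC without normal 5 and recurrent 2, 3 and 6 (limma camera adjusted p = 0.908). Lists not called as reported were called in some settings, p53 targets (adjusted p = 0.0354) in PTC/N and trachea and cartilage in rec/ATC (0.0181) and rec/N (0.016) without those 4 arrays, and in ATC/PTC neutrophil (0.0243) and interferon (0.0291) with the title series as a block and hypoxia (0.0475) with means of probe sets. Hgf between recurrent and ATC was called with array weights only (1.06, limma adjusted p = 0.0225). Leaving out single arrays, the Hgf difference was 0.48 to 0.82 and that of Met 0.56 to 0.98. Met with Hgf had r from 0.278 (without recurrent 8) to 0.728 (without recurrent 6), and -0.00361 without the 2 farthest arrays. Met with its neighbours had r from 0.454 (without recurrent 1) to 0.927 (without recurrent 6), and -0.0314 without the 2 farthest. Apart from the settings that test more features or fewer samples, the cause was not tested. Array signal limits what can be seen near the floor, and 9 recurrent arrays with a wide spread limit what can be said of that group.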

Other observations

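Scd3, Mogat1, Elovl3, Krt79 and Mc5r stood high on recurrent array 6, all chosen after their values were seen and not tested as a group, while the adipocyte list mean there was -3.12. Log2 levels, with the highest other tumour and the highest normal pool in brackets, were 14.66 for Scd3 (5.96, 5.51), 14.26 for Mogat1 (4.71, 6.62), 13.99 for Elovl3 (7.60, 7.5), 12.22 for Krt79 (9.12, 6.78) and 9.44 for Mc5r (5.16, 4.81). Scd1 (14.74) and Cidea (13.64) were above the other tumours (11.31 and 9.76) but nearer to the highest normal pool (14.50 and 12.09). The mean of the skeletal muscle list ran from -4.98 to 3.35 over the recurrent arrays, relative to the normal mean, and that of the trachea and cartilage list from -1.37 to 4.09.

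Other runs of neighbouring genes stood high on single recurrent arrays, also chosen after their values were seen. On array 7 a run from Dctn2 to Gli1 had a smallest deviation of 2.04 from the other tumours, reached in 1 of 1000 shuffled gene orders, and Gli1, Hhip and Ptch1, which belong to the hedgehog pathway, were at 12.54, 11.76 and 13.94. On array 2 the runs from Il17rc to Vhl, Mtmr14 to Tada3 and Myc to Asap1 had smallest deviations of 1.96, 1.92 and 1.79, each reached in 0 of 1000. Runs of related genes also stood high, with 3.27 for Lce1 genes on array 1, above the run with Met there, and 6.74 on array 5, 1.40 for Ms4a genes on array 8, also above the run with Met there (1.25), and 2.32 for matrix metalloproteinase genes on array 2.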
